A study of Mus musculus with 4 samples.

How the data were processed

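Mouse heart tissue of 4 groups was measured, with 1 array per group: wild type atria, Mef2a knockout atria, wild type ventricles and Mef2a knockout ventricles. Per the labels' protocols, chambers were dissected from mice 2 months old and total RNA was extracted with Trizol. RNA of 7 mice was pooled in equal molar amounts for each array. The pools mixed males and females, with the number of each not given in the sources used here. RNA was labelled with biotin through a whole-transcript amplification kit from Ambion and a terminal labelling kit from Affymetrix. Such arrays read many short probes spread over each gene.

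The deposited values are log2 intensities, 1 per probe set, which per the submitters' processing notes were made with RMA and the affy package. RMA corrects the background, evens out the distributions of the arrays and summarises the probes of a probe set. It compresses differences between values near background. The versions of both tools, the array design and the version of the probe set definitions were not given in the sources used here. The 4 columns did not share 1 distribution, so some step after quantile normalization, or a filter on probe sets, cannot be excluded. Scanner files were not used here.

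The table held 21212 probe sets, each named by a gene number. The platform annotation paired 18786 of them with 1 gene symbol and 6 with several symbols, and 2420 had no entry in it. Symbols were updated through a RefSeq gene table of mouse assembly GRCm38.p6, with 18775 matched by gene number, 6 by accession and 5 kept as annotated. That table was used for names and for the order of neighbouring genes, and no coordinates are given because the build behind the array was not named. The 2426 probe sets without exactly 1 symbol were left unnamed and counted apart. For 5 symbols with more than 1 probe set, the probe set with the highest mean over the 4 arrays was kept, which left 18781 genes.

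With 1 pooled array per group there is no replicate error within a group, and no test of a difference within a chamber, or of a difference between chambers in the knockout effect, was possible. A fit of genotype with the chamber as a block would leave 1 residual degree of freedom. It was not run, because its error would measure how the knockout effect differs between chambers and not the variation between animals. The number of arrays limits the precision of every value. Each comparison is the difference of 2 log2 values. A gene was counted as higher or lower when it reached 1.5-fold for knockout against wild type, or 2-fold for atria against ventricles. The brighter array of the pair also had to reach the median of all values of the table, 5.71 on the log2 scale, which is called the floor. The stated comparisons were knockout against wild type in atria, knockout against wild type in ventricles, and wild type atria against wild type ventricles. Knockout atria against knockout ventricles was added to set beside the last. The wild type chamber comparison shares an array with each knockout comparison, while the 2 knockout comparisons share none.

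The comparisons, the fold and floor, and 43 gene lists with 906 genes were fixed before the data were examined. Of the listed genes 816 had a named probe set. They covered cardiomyocyte functions, metabolism, states of the tissue, chamber markers, markers of other cell types, and control lists. For each list the median log2 ratio of its members above the floor was set among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. The resulting percentile describes these arrays and is not a test of the genotype. Lists with fewer than 5 members above the floor have values only. Genes were named by a rule fixed in advance. It took the 12 highest and 12 lowest genes past the fold in each stated comparison and up to 4 members past the fold per list and direction, or the 2 members with the largest size where none passed. It also took up to 10 genes past the fold the same way in both chambers and 10 in opposite ways, the MEF2 family, Xist and Y-linked genes. Predicted genes, small RNAs, immune receptor segments and olfactory or pheromone receptors were counted but not named. Further list members and partner genes are given as values where a list is described.

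The overlap of the 2 knockout comparisons was set beside the number that independent lists would share. Correlations are across genes, which are not independent replicates, so they carry no p-value. Olfactory receptor genes, which heart tissue was not assumed to express, described the spread near background. Exact 95% binomial intervals for shares of genes are Clopper-Pearson intervals. They cover counting error over genes only, not the variation between animals or arrays.

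The counting step was tested on simulated data made from the wild type values of 18781 genes, with 100 genes changed at each of 2 fold sizes. The changed genes were drawn from those at least 2 log2 units above the floor, so recovery near the floor was not tested. The noise was normal, with the scaled median absolute deviation of each real comparison as its width. That was 0.21 in atria and 0.12 in ventricles, below the standard deviations of 0.26 and 0.19, so the wider tails of the real ratios were left out. For atria, 99% of the 2-fold and 100% of the 4-fold changes passed 1.5-fold in the right direction, and 53 unchanged genes passed. For ventricles, 100% of the 2-fold and 100% of the 4-fold changes passed, and 0 unchanged genes did. Of 40 simulated lists of 20 genes moved by 0.2, 95% (atria) and 100% (ventricles) lay outside the central 95% of the random lists. Of 40 lists that were not moved, 2.5% (atria) and 7.5% (ventricles) did. These lists were drawn at random from genes with independent noise, so lists whose genes vary together were not tested.

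Alternatives fixed at the same stage were median centring, quantile normalization, removal of the trend with level by lowess with a span of 0.3, no floor, a floor at the 75th percentile, and a stricter fold. The others were the mean over the probe sets of a gene, all probe sets, and leaving out markers of other cell types and sex-linked genes. The stricter fold was 2-fold for the knockout comparisons and 4-fold for the chambers. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.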

Results

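Gene expression was measured in dissected atria and ventricles of adult mice of 2 genotypes, wild type and knockout for Mef2a, which encodes a MADS-box transcription factor of striated muscle. The design has 4 groups with 1 array each, and every array carried RNA pooled from 7 mice. There were no replicate arrays, so no difference below could be set against a replicate spread, and all are descriptions of these pools. The median probe set value was 5.72 on the wild type atria array, 5.75 on the knockout atria array, 5.69 on the wild type ventricles array and 5.66 on the knockout ventricles array (log2 intensity). The interquartile range was 2.97 on the knockout atria array and 3.21, 3.18 and 3.19 on the wild type atria, wild type ventricles and knockout ventricles arrays, so that values on the knockout atria array were more compressed. Across probe sets, Pearson's correlation was 0.992 between the atrial arrays, 0.996 between the ventricular arrays and 0.978 between the wild type atria and wild type ventricles.

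The targeted gene was read first. Mef2a stood at 10.32 on the wild type and 10.41 on the knockout-labelled atria array, and at 10.28 and 10.34 on the ventricular arrays, so its signal was not lower on either knockout-labelled array. The probe set summarises probes over the gene, and which part was deleted was not given in the sources used here. The signal therefore does not check the genotype labels, and every direction below rests on those labels. The related family members differed by less than 1.5-fold. Mef2b was higher by 0.36 in atria and 0.30 in ventricles, but lay below the floor on every array except knockout-labelled atria (5.77). Mef2c was higher by 0.14 and 0.04, and Mef2d differed by 0.06 and −0.04. These signs were the same under median centring, quantile normalization and lowess centring.

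**Figure D1:**
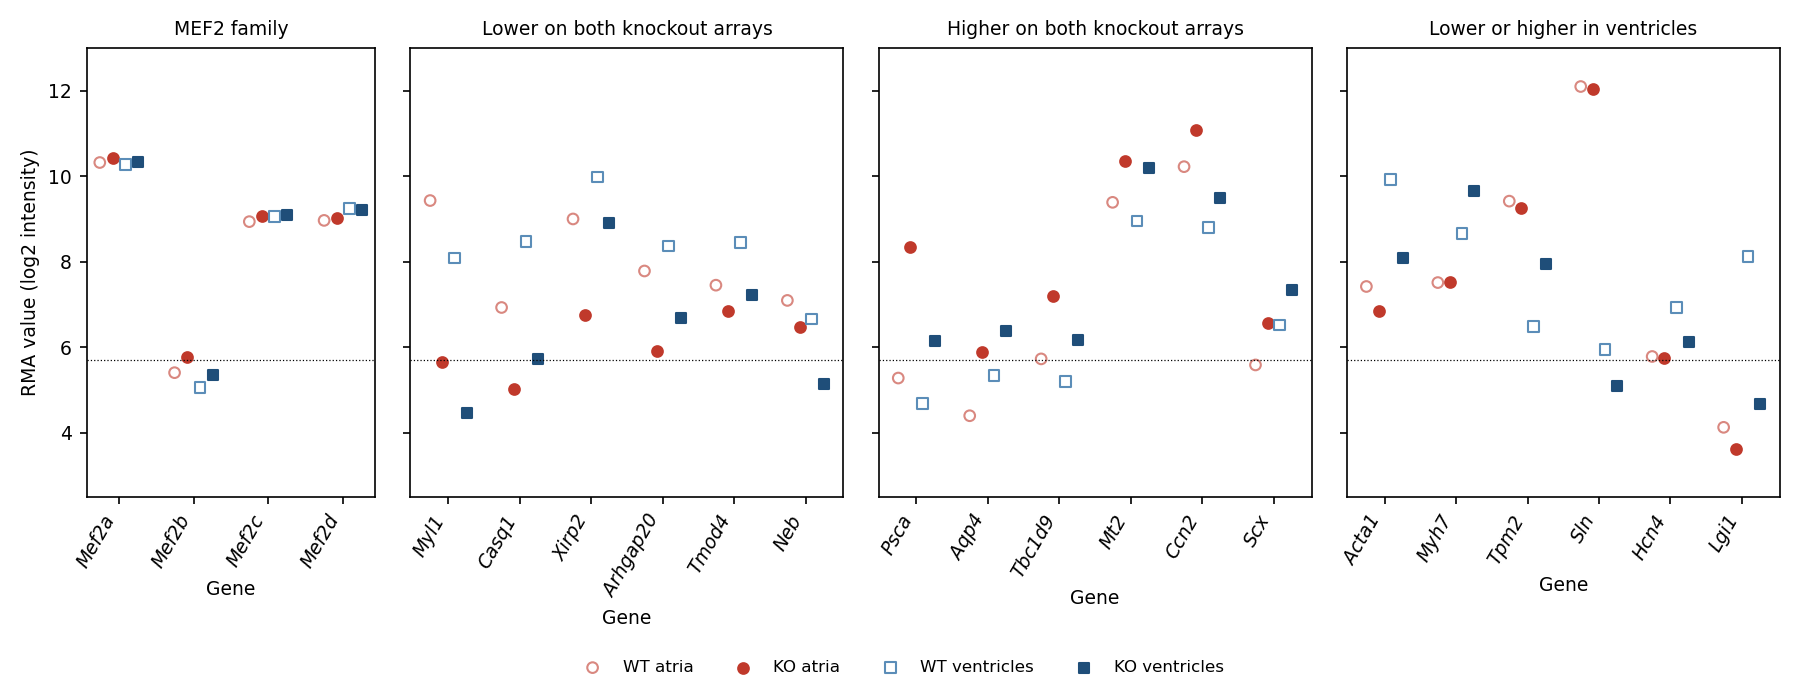
RMA values (log2 intensity, vertical axis) of 22 genes on the 4 arrays, with open symbols for wild type and filled symbols for knockout-labelled pools, circles for atria and squares for ventricles, 1 pooled array per symbol; the dotted line is the floor of 5.71. Mef2a lies between 10.28 and 10.41 on all 4 arrays, while Myl1 is at 9.43 and 8.09 in wild type and at 5.66 and 4.47 in knockout-labelled atria and ventricles.

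Knockout against wild type atria asked which transcripts differ in the upper chambers of mice labelled as lacking MEF2A. The lowest gene was Myl1, the alkali light chain of fast skeletal muscle myosin, with a log2 ratio of −3.77, or 13.7-fold lower. Other muscle genes followed: Xirp2, an actin-binding protein of costameres and intercalated discs, at −2.24, Casq1, the skeletal type of the calcium-binding protein calsequestrin, at −1.91, and Cavin4, a muscle caveolar coat protein, at −1.83. Receptor genes were also among the lowest, with Mrgprh at −2.10, the prostaglandin F receptor gene Ptgfr at −2.02 and the neuropeptide Y receptor gene Npy1r at −1.74. So were the platelet chemokine gene Ppbp at −2.12, Car3 (carbonic anhydrase 3) at −2.09, Arhgap20 at −1.87, Hadhb, a subunit of the mitochondrial trifunctional protein, at −1.74, and Cyp2e1 at −1.72. The highest were Psca, which encodes a surface glycoprotein, at 3.07 (8.41-fold), Ppp1r17 at 2.35, Scgb1c1 at 1.67, the prostaglandin D synthase gene Ptgds at 1.58, the water channel gene Aqp4 at 1.49 and Tbc1d9. Vsnl1, a neuronal calcium sensor, was higher by 1.32, Prh1 by 1.22, Gemin8 by 1.19, P4ha3 and the calcium channel subunit gene Cacna2d2 by 1.15, and Bmp5 by 1.02.

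In atria 305 of 10050 genes above the floor passed 1.5-fold, 103 higher and 202 lower, and 65 passed 2-fold, 17 higher and 48 lower. The balance of higher and lower genes depended on the floor, with 289 higher and 269 lower when none was set and 35 and 80 with a floor at the 75th percentile. Under median centring the counts were 127 and 178. The trend with level ran through this comparison: the median log2 ratio was 0.19 in decile 3 of genes by mean level and −0.04 in decile 10, against 0.00 and 0.02 in ventricles.

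**Figure D2:**
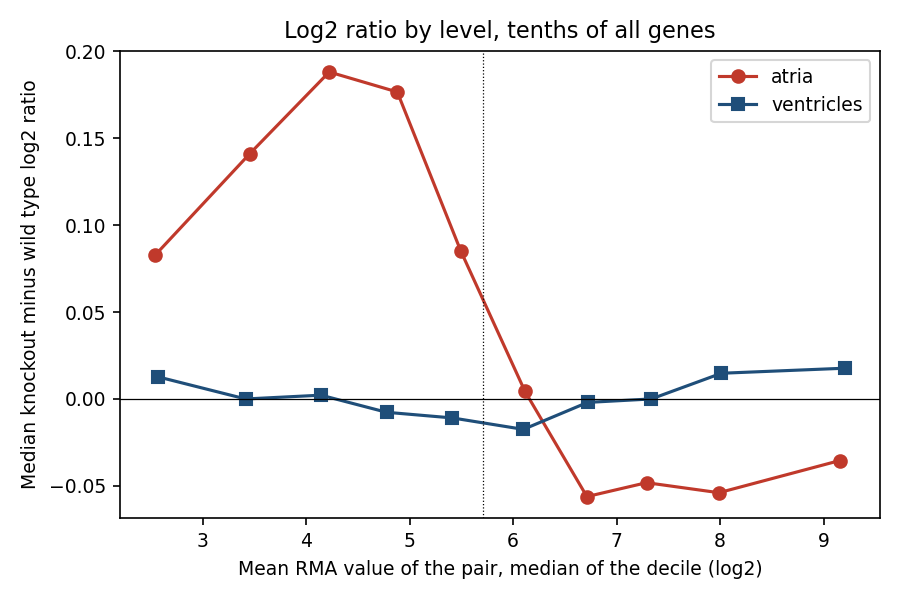
Median knockout minus wild type log2 ratio (vertical axis) against the mean RMA value of the pair (horizontal axis, log2), over deciles of all 18781 genes, with circles for atria and squares for ventricles; the dotted line is the floor. The atrial medians run from 0.19 at low levels to −0.06 above the floor, while the ventricular medians stay between −0.02 and 0.02.

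Among muscle gene groups in atria, skeletal muscle genes stood apart. All 8 members above the floor had negative log2 ratios, with a median of −0.41, at percentile 0.05 of the random lists. Past 1.5-fold were Casq1, the fast troponin T gene Tnnt3 (−0.66) and the fast troponin I gene Tnni2 (−0.59). Of 29 costamere genes, Xirp2, the integrin gene Itga7 (−0.94) and the ankyrin gene Ank2 (−0.64) were lower and 0 were higher, and the list median of −0.06 lay inside the central range, with its sign turned by quantile normalization. At the Dlk1-Dio3 locus, an imprinted noncoding RNA cluster, Dlk1 was at 0.24 and Meg3 at 0.35 in atria, and at 0.16 and −0.13 in ventricles. None of 27 sarcomere genes passed, with Acta1, the skeletal type of alpha actin, lowest at −0.58 and a median of −0.08. Calcium handling genes had a median of −0.10 over 26 genes, with Casq1 lower and Cacna2d2 higher. None of 19 cardiac transcription factors passed, where Hand1 (0.27) and Srf (0.24) had the largest sizes and the median was 0.02. Of 22 ion channel and gap junction genes, the inward rectifier gene Kcnj2 passed 1.5-fold, lower at −0.79. Of 15 genes of the conduction system, Vsnl1 and the homeobox gene Irx3 (0.61) were higher and Cpne5 (−0.61) was lower. Both directions also occurred among hormone signalling genes, with Ptgds higher and the angiotensin receptor gene Agtr1a (−1.08) and the cyclooxygenase gene Ptgs2 (−0.63) lower. Of 22 atrial identity genes, Ntm and the orphan receptor gene Nr2f1 (−0.69) were lower and 0 were higher.

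Markers of other cell types also differed between the atrial pools. Fibroblast and extracellular matrix genes had a median of −0.25 over 29 genes, below all 10000 random lists. Of these, 20 were negative, Lum (−0.84), Pdgfra (−0.63) and Dpt (−0.62) passed 1.5-fold, and Ccn2, encoding connective tissue growth factor, was higher at 0.86. Endothelial genes had a median of 0.14 over 25 genes, above all random lists, with 0 past 1.5-fold and Robo4 highest at 0.36. The cartilage and tendon list had a median of 0.24 over 9 genes (percentile 99.9), with the tendon transcription factor gene Scx higher at 0.98. Adipose genes had a median of −0.18 over 14 genes (percentile 2.44), where Car3, Cyp2e1, Retn (−1.07) and Scd1 (−0.93) were lower and Thrsp was higher at 0.59. The adipose genes Adipoq (−0.73), Plin1 (0.04), Lep (0.20) and Cidec (0.12) lay below the floor on both atrial arrays. Among smooth muscle genes Cnn1 was lower at −1.29 and Acta2 higher at 0.61, with a median of 0.04. Epicardial genes had a median of 0.00 with Krt18 higher at 0.60. Medians inside the central range were 0.04 for macrophages, 0.02 for lymphatic endothelium and 0.12 for neurons and glia. Fatty acid uptake and oxidation genes had a small positive median of 0.07 over 30 genes (percentile 99.7), with Hadhb the only member past 1.5-fold. Genes of oxidative phosphorylation had a median of −0.04 over 43 genes, with its sign turned under another scaling, the citrate cycle list −0.08 with Tfam lower at −0.60, and glycolysis 0.04. The 14 genes next to Mef2a had a median of −0.24 (percentile 0.24), with 0 past 1.5-fold and Ttc23 lowest at −0.38. Across the 34 lists with a percentile, 4 lay below and 3 above the central 95% of their random lists. Chance gives 1.7 in all only for independent lists whose genes also vary independently, which was not checked for these lists.

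Knockout against wild type ventricles asked the same question in the lower chambers. Myl1 was again the lowest gene, at −3.62 (12.3-fold lower). It was followed by Lgi1, a secreted protein best known from neurons, at −3.44, Casq1 at −2.76, B3galt2 at −2.47, Fam81a at −2.13 and Acta1 at −1.82. Next came Arhgap20 at −1.69, Tmprss13 at −1.59, the thin filament gene Neb (nebulin) at −1.51, Abcb4 at −1.48, Tnfaip8 at −1.46 and Mrgprh at −1.45. The highest were Thrsp, a regulator of lipid synthesis, at 1.83, the endocytic receptor gene Cubn at 1.77, Prrg4 at 1.64, the sodium-proton exchanger gene Slc9a3 at 1.59, the beta tropomyosin gene Tpm2 at 1.47 and Abca4 at 1.45. Psca (1.44), Pcbd1 (1.30), Ddc (1.27), the metallothionein gene Mt2 (1.24), Hyal1 (1.07) and Pde3b (1.06) came next. In total 117 of 9712 genes above the floor passed 1.5-fold, 50 higher and 67 lower, and 36 passed 2-fold, 14 higher and 22 lower. Without a floor the counts were 99 higher and 121 lower.

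Stress and fetal cardiac genes were higher as a group in ventricles, with a median of 0.27 over 16 genes, above all random lists, 11 of them positive and 5 negative. The slow myosin gene Myh7 (0.99) and Ccn2 (0.69) were at least 1.5-fold higher and Acta1, also a member, at least 1.5-fold lower. Of the natriuretic peptide genes, neither past 1.5-fold, Nppb was at 0.45 and Nppa at −0.01. In atria the list median was 0.05, with Ccn2 and Acta2 higher and Nppb higher by 0.47. Oxidative stress and detoxification genes had a ventricular median of 0.18 over 22 genes, above all random lists, with 18 positive, Mt2 past 1.5-fold and Nqo1 at 0.43. Circadian clock genes had a median of 0.17 (percentile 99.99) with Ciart past 1.5-fold at 0.62. Interferon response genes had a median of 0.11 (percentile 99.97) and immediate early genes 0.12 (percentile 99.9), each with 0 members past 1.5-fold, led by Cxcl9 at 0.55 and Ier3 at 0.56. The corresponding atrial medians were −0.03, 0.02, 0.00 and 0.05, where the signs for oxidative stress and interferon genes turned under another scaling. Fatty acid genes had a median of 0.06 over 31 genes (percentile 99.5) with 0 past 1.5-fold, and Pdk4 and Angptl4 at 0.31 and 0.24.

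The atrial identity list had a median of −0.20 over 17 genes in knockout-labelled ventricles, below all random lists. Of these genes 11 were negative and 6 positive. Sarcolipin, the calcium pump regulator encoded by Sln, passed 1.5-fold at −0.85, from 5.95 to 5.09, and the atrial light chain genes Myl7 and Myl4 stood at −0.54 and −0.32. The 6 positive members were the gap junction gene Gja5 (0.51), Dkk3 (0.39), Clu (0.21), Kcnj5 (0.20), Kcnk3 (0.20) and Pam (0.15). Gja5 and Dkk3 reached the floor only on the knockout-labelled ventricles array, from 5.59 and 5.34 on the wild type array. Sln reached it only on the wild type array. Genes at least 2-fold higher in atria, and above the floor in ventricles, did not show a fall of the list's size. Chosen on the wild type pair, 245 genes had a median of 0.03 (45.7% negative). Chosen on the knockout-labelled pair, 212 had −0.02 (53.3% negative). Each choice shares an array with the comparison, the first pushing the ratio up and the second down. Neither set was among the lists fixed beforehand. Ventricular identity genes had a median of −0.02, with Casq1 lower and Myh7 higher. Macrophage genes had a median of −0.12 (percentile 0.02), with 15 of 19 negative and Lyz1 past 1.5-fold the other way at 0.61. Fibroblast and extracellular matrix genes had a median of −0.08 (percentile 0.07), with 21 of 28 negative and Ccn2 higher. Of 26 sarcomere genes, Acta1 and Mybpc2 (−1.03), the fast type of myosin-binding protein C, were lower and Myh7 was higher, with a median of −0.03. Among ion channels, the pacemaker channel genes parted, with Hcn4 lower at −0.80 and Hcn2 higher at 0.64. Thrsp, Car3 (0.74) and Cidea (0.62) were higher among 11 adipose genes, Npr3 (0.68) among 25 endothelial genes and Fgl2 (0.63) among 5 lymphatic genes, with 0 members of these lists past 1.5-fold lower. Of the 34 lists with a percentile, 3 lay below and 6 above the central 95%.

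**Figure D3:**
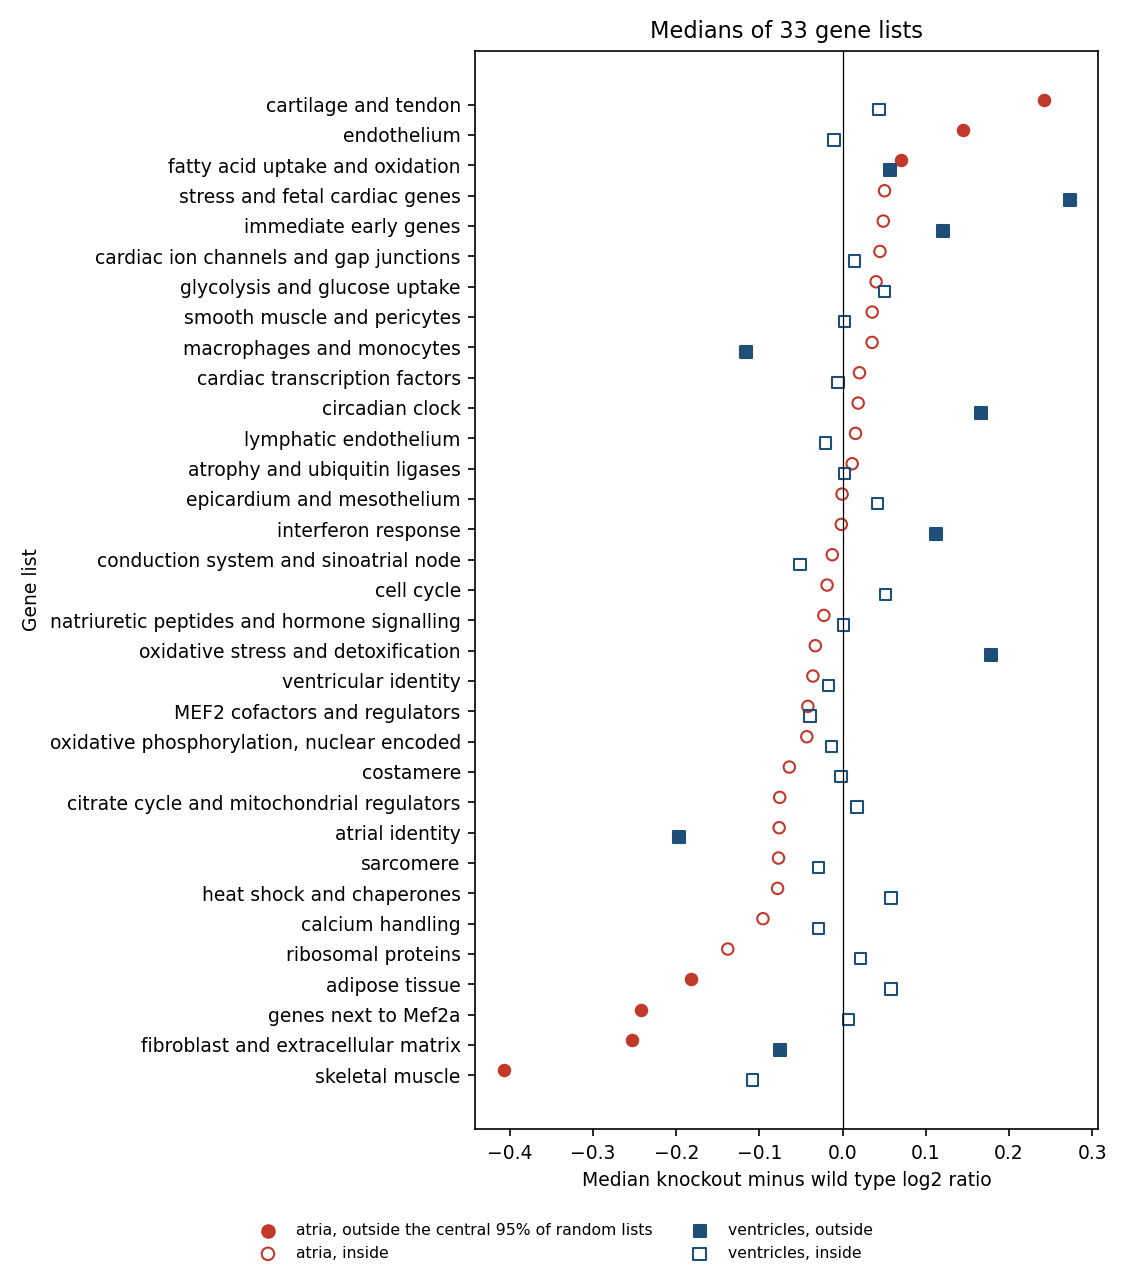
Median knockout minus wild type log2 ratio (horizontal axis) of the 33 gene lists (vertical axis) with a percentile in both comparisons, circles for atria and squares for ventricles, filled where the median lay outside the central 95% of 10000 random lists. Skeletal muscle is lowest in atria at −0.41, and stress and fetal cardiac genes are highest in ventricles at 0.27.

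The knockout effect was then set side by side in the 2 chambers, whose comparisons share no array. Whether the same mice gave both chambers is not stated here. If they did, any difference between the animals of the 2 genotypes would appear in both comparisons, and the overlap would not be a replication. Of 9436 genes above the floor in both, 34 passed 1.5-fold in the same direction, 10 higher and 24 lower, where independent lists would share 0.25 and 0.90. Lower in both were Myl1, Casq1, Arhgap20, Mrgprh, Xirp2 (−2.24 in atria, −1.06 in ventricles), Abcb4 (−1.07, −1.48), Armh4 (−1.56, −1.05) and the ubiquitin ligase subunit gene Asb4 (−1.30, −1.02). Higher in both were Psca (3.07, 1.44) and Aqp4 (1.49, 1.04). The 34 also held Tmod4, a tropomodulin of striated muscle, at −0.61 and −1.24, Neb at −0.61 and −1.51, Mt2 at 0.97 and 1.24, Scx at 0.98 and 0.81, and Ccn2 at 0.86 and 0.69. Car3 and Gm10334 went in opposite ways: Car3 was at −2.09 in atria and 0.74 in ventricles, and Gm10334, named after its values were seen, at 0.78 and −0.66.

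Of 220 genes past 1.5-fold in atria and above the floor in both, 173 (78.6%) had the same sign in ventricles, and of 92 past it in ventricles, 79 (85.9%) had the same sign in atria. Over all 9436 genes the share was 57.7%. Pearson's correlation of the 2 log2 ratios across genes was 0.36 and Spearman's 0.26. Over all genes, 269 passed 1.5-fold in atria alone and 81 in ventricles alone, which includes genes below the floor in the other chamber. The standard deviation of log2 ratios was 0.26 in atria and 0.19 in ventricles. The difference between chambers had no test. With a floor at the 75th percentile 9 genes were shared.

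**Figure D4:**
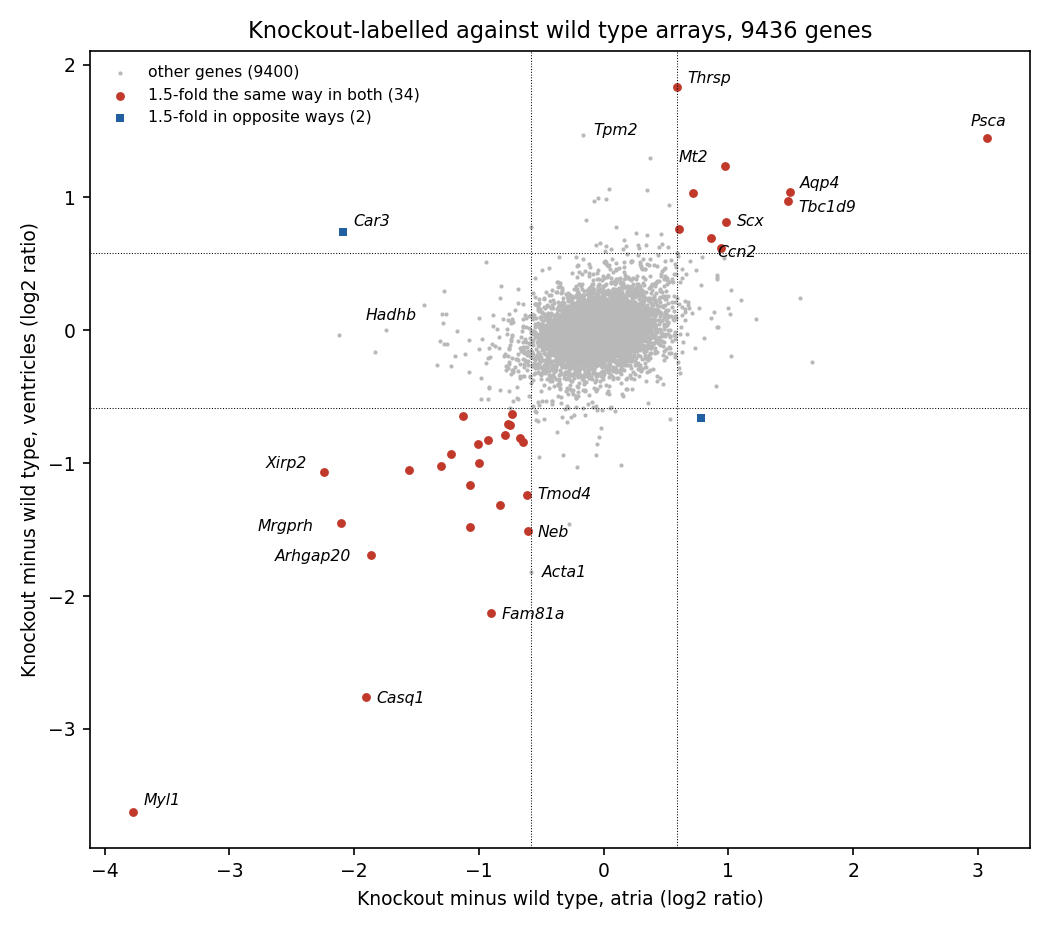
Knockout minus wild type log2 ratios of 9436 genes above the floor in both comparisons, atria on the horizontal and ventricles on the vertical axis, 1 pooled array per group; dotted lines mark 1.5-fold. The 34 genes past it the same way are red, with Myl1 at −3.77 and −3.62 farthest out, and the 2 genes past it in opposite ways are blue squares.

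Wild type atria against wild type ventricles asked what separates the chambers. The genes higher in atria were led by the growth factor gene Bmp10 at 7.04, Sbk3 at 6.16, Sln at 6.15, the iron hormone gene Hamp at 6.07, Mybphl at 5.86, Fgf12 at 5.45, Dkk3 at 5.30 and Myl7 at 5.11, followed by Cxcl13 (4.84), Npy1r (4.41), Fbxw18 (4.35) and Mlana (4.11). Higher in ventricles were Lgi1 at −3.99 (atria minus ventricles), the homeobox gene Irx4 at −3.43, B3galt2 at −3.35, Lrtm1 at −3.32, Fgf16 at −3.24 and Tesc at −3.15. They were followed by the ketone enzyme gene Bdh1 (−3.05), Rpl3l (−2.99), Gbp6 (−2.98), Smyd2 (−2.81), Myot (−2.67) and Sh3rf2 (−2.59). Of 10034 genes above the floor, 390 were at least 2-fold higher in atria and 222 in ventricles, and 92 and 28 at least 4-fold.

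Chamber marker genes were counted first. Of 23 atrial identity genes 19 were at least 2-fold higher in atria, with a median of 1.81 above all random lists, and Kcna5 alone was 2-fold the other way (−1.04). Of 18 ventricular identity genes 10 were higher in ventricles and 0 in atria, with a median of −1.10 below all random lists. Metabolic gene lists had negative medians in atria against ventricles. At least 2-fold lower in atria were 9 of 31 fatty acid, 2 of 27 citrate cycle, 0 of 43 oxidative phosphorylation and 1 of 21 glycolytic genes. The medians were −0.82 for fatty acid uptake and oxidation over 31 genes, −0.50 for the citrate cycle over 27 and −0.35 for oxidative phosphorylation over 43, of which 42 were negative, all below every random list. Examples were Plin5 (−1.54), Ech1 (−1.26) and Ucp3 (−1.21), Perm1 (−1.39) and Sucla2 (−1.26), and among glycolytic genes Hk2 (−1.20), with a list median of −0.30 (percentile 0.98).

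Cell type markers differed as well between the wild type chambers. Epicardial genes were higher in atria, with a median of 1.26 over 17 genes, 11 past 2-fold and Gpm6a (2.97) and Upk1b (2.85) highest. Fibroblast and extracellular matrix genes had a median of 0.65, with 8 of 30 past 2-fold, among them Mfap4 (2.03) and Comp (1.73). Natriuretic peptide and hormone genes had a median of 0.67, with Npr3 at 2.74, Adm at 2.17, and Nppa also past 2-fold. All 3 medians lay above every random list. Lymphatic (0.80), cartilage and tendon (0.57) and neuronal (0.57) medians were also in the upper tail. Endothelial (−0.32) and smooth muscle (−0.41) medians were in the lower tail, while Npr3, Plvap (2.63) and Vwf (1.73) were endothelial genes higher in atria. Red cell genes had a median of −0.57 over 4 genes. Calcium handling genes had a median of −0.23 (percentile 1.01), with Sln and Cacna2d2 (2.98) higher in atria and Cacna1c (−1.02) and Cacna2d1 (−1.10) higher in ventricles. Of the 34 lists, 8 lay below and 10 above the central 95%.

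The same contrast between the knockout-labelled pools shares no array with the wild type one. There 350 of 10120 genes were at least 2-fold higher in atria and 288 in ventricles. Of the 390 genes higher in wild type atria, 275 (70.5%, exact 95% interval 65.7 to 75) were also at least 2-fold higher in knockout-labelled atria. Of the 222 higher in wild type ventricles, 158 (71.2%, exact 95% interval 64.7 to 77.0) were also higher in knockout-labelled ventricles. Myl7, Bmp10 and Sln were among those higher in atria in both genotypes, whereas Ppbp went from 2.52 in wild type to 0.43. Lgi1 went from −3.99 to −1.05, still past 2-fold. It stood at 3.63 and 4.68 on the knockout-labelled atria and ventricles arrays, both below the floor. A kept gene also had to reach the floor in the knockout-labelled pair, so Lgi1 was not among the 158. At the stricter 4-fold in both pairs the shares were 75% of 92 genes for atria and 53.6% of only 28 genes for ventricles, with no interval computed.

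**Figure D5:**
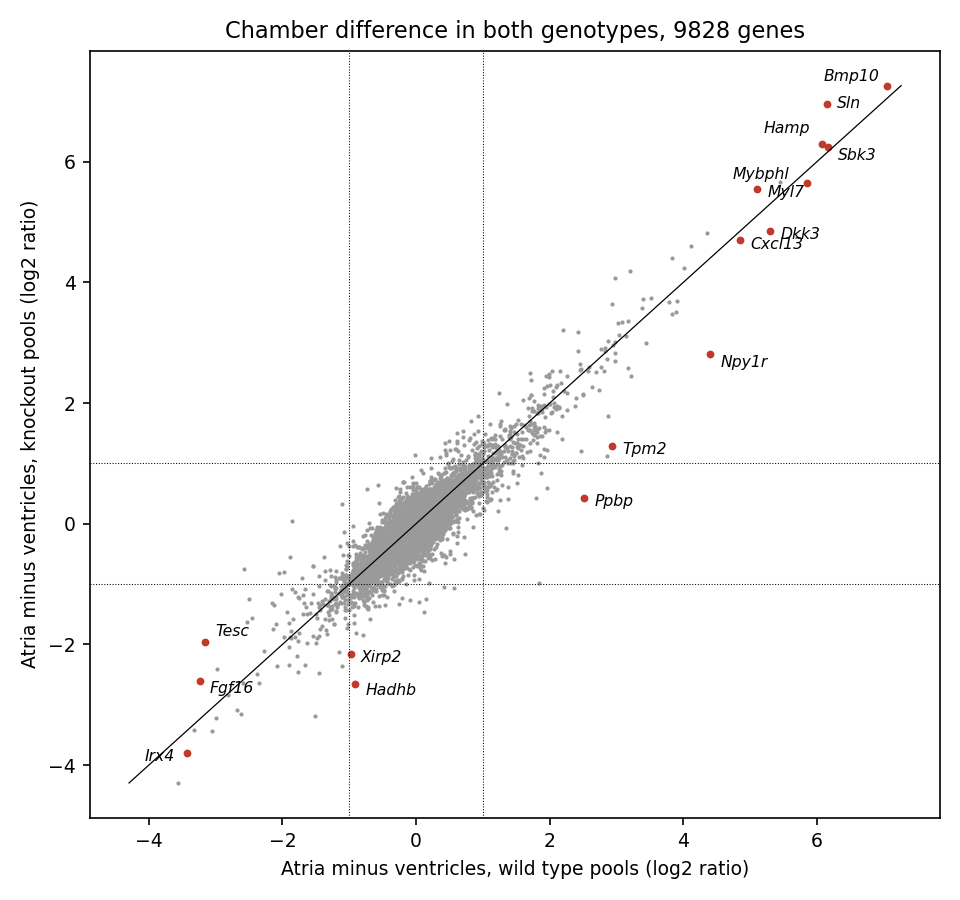
Atria minus ventricles log2 ratios of 9828 genes above the floor in both pairs, wild type pools on the horizontal and knockout-labelled pools on the vertical axis, with the line of equal values and dotted lines at 2-fold. Bmp10 (7.04 in wild type) lies near the line, while Ppbp (2.52 and 0.43) and Npy1r (4.41 and 2.81) lie below it.

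The sex balance and the noise near background were read from control genes. Xist, expressed from the inactive X chromosome, stood at 9.97 and 9.63 on the wild type and knockout-labelled atria arrays and at 9.35 and 9.20 on the ventricular arrays. The Y-linked Eif2s3y stood at 7.69, 7.42, 7.87 and 7.89 and Uty at 7.19, 7.16, 7.15 and 7.10 in the same order, all above the floor. The Y-linked Kdm5d stood at 5.42, 5.21, 5.74 and 5.58, above the floor only on the wild type ventricles array. The log2 ratios of 1068 olfactory receptor genes had a standard deviation of 0.21 in atria and 0.21 in ventricles, with 29 (2.72%) and 17 (1.59%) past 1.5-fold. Their median was 0.12 in atria and 0.02 in ventricles. Lists inside the central range in both knockout comparisons included heat shock and chaperone genes (−0.08 in atria, 0.06 in ventricles), cell cycle genes (−0.02, 0.05), MEF2 cofactors (−0.04, −0.04) and atrophy genes (0.01, 0.00). The atrial signs of the cell cycle and cofactor lists and the ventricular sign of the atrophy list turned under another scaling. Ribosomal protein genes had a median of −0.14 in atria (percentile 3.02) and 0.02 in ventricles.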

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

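Of the tests in this part, only the share of lower atrial genes further down than the lowest fibroblast marker was fixed before its result was seen. All the others were chosen after it, or after related values had been seen.

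Car3, the carbonic anhydrase 3 gene, drew attention because the knockout difference ran in opposite directions in the 2 chambers, at −2.09 in atria and 0.74 in ventricles. The difference was not tested, since each group has 1 array. Probe sets without a single gene symbol were outside the comparisons above. Of these, 89 passed 1.5-fold between knockout-labelled and wild type atria, 15 between the ventricular arrays, and 45 passed 2-fold between the wild type chambers.

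More genes passed 1.5-fold in atria (305) than in ventricles (117), and removing the trend with level, which would take away an excess made by the compressed range of the knockout atria array, left the atrial total 2.68 times the ventricular one. Noise near background is not the whole cause, as the ratio of totals was 2.05 with the floor at the 75th percentile. For genes nearer the floor it cannot be told apart from other causes. The standard deviation of olfactory receptor log2 ratios was 0.986 times as wide in atria, while 29 against 17 of these genes passed 1.5-fold. In decile 5 of level the standard deviation over genes was 0.32 in atria against 0.20 in ventricles. It was also wider in atria for the brightest genes, at 0.20 against 0.14 in decile 10. A higher floor does not remove a spread that is wider at high levels too, and the cause of that spread was not tested. A lower share of fibroblasts in the knockout-labelled atria pool cannot be told apart from a genotype effect within cells: 35.6% of the 202 lower genes lay further down than the lowest fibroblast marker (Lum, −0.84), which met what a lower share was said beforehand to give, but 37.9% of the 103 higher genes lay as far the other way, so that share does not bear on fibroblasts, and without the markers of other cell types the totals were 285 and 106. Array quality and a stronger genotype effect in atria also stay open, with 1 array per group, so the pattern is not called biological.

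Among the 24 genes lower in both chambers were the muscle genes Myl1, Casq1, Xirp2, Neb and Tmod4. Skeletal muscle carried over into both wild type pools would bring its abundant transcripts, but 9 fast skeletal genes (Mylpf, Myh4, Myh1, Tnnt3, Tnni2, Tnnc2, Pvalb, Actn3 and Atp2a1) reached at most 6.37 on a wild type array, close to the floor, and had medians of −0.17 in atria and 0.05 in ventricles against −3.77 and −3.62 for Myl1, which argues against it as the whole cause. A small contribution stays open, as the skeletal muscle list had all 8 members negative in atria (median −0.41), with Tnnt3 (−0.66) and Tnni2 (−0.59) lower, and 5 of 6 negative in ventricles (median −0.11, percentile 3.03), with Casq1 and Mybpc2 (−1.03) lower. Passenger genes among the 100 named genes nearest to Mef2a do not account for the pattern, since 0 of them were among the 34 genes past 1.5-fold the same way. Of the 100, 54 were above the floor in both comparisons, where 0.19 would be among the 34 at the rate of all genes. Genes further out were not examined. In atria the list of genes next to Mef2a had a median of −0.24, with 11 of 14 negative and 0 past 1.5-fold, and in ventricles a median of 0.01 over 13 genes. A loss of transcription that depends on MEF2A is a hypothesis, found and tested on the same 4 arrays, and strain differences away from the locus or handling that separated the genotypes were not tested and could also give differences shared by the chambers.

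The atrial identity list had a median of −0.20 in knockout-labelled ventricles, with 11 of 17 genes negative, 6 positive and only Sln past 1.5-fold. Less atrial tissue in that pool cannot be told apart from an effect of the genotype. The share of atrial RNA that would give all of the Sln difference is 0.63%. It would put 17 other abundant atrial genes at a median of −0.06, against 0.10 observed (standard error 0.042). Of these genes 4 were negative and 0 at least 1.5-fold lower, and the median of observed minus expected values was 0.17 (standard error 0.078). The standard errors in this paragraph come from resampling the genes of a set. Genes are not independent replicates, and these errors hold no variation between animals or arrays. The values of the 17 genes do not settle the question. Hamp, Sbk3 and Sbk2 among them lay below the floor on both ventricular arrays, where RMA compresses differences and an expected fall cannot show in full. Sln itself went from 5.95 to 5.09, below the floor. Choosing the genes on the wild type arrays also pushes the ratio up. For 13 genes chosen on the knockout-labelled arrays, which pushes it down, the observed median was 0.04 with 6 negative. Their median of observed minus expected values was 0.16 (standard error 0.103). The same share would put the other 16 list genes at a median of −0.030, against −0.15 observed, with a median of observed minus expected values of −0.13 (standard error 0.122). It would put Myl7 at −0.35, against −0.54 observed, and Dkk3 at −0.41, against 0.39 observed. Dkk3 went from 5.34, below the floor, to 5.73, so an expected fall could not show in full for it either. A genotype effect on part of the list may be present and stays a hypothesis.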

How the results depend on the processing

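No test in this part was chosen after its result was seen. All 13 summaries of the comparisons stayed within 1.5 times their value, or within their spread, under median centring, quantile normalization, lowess centring, the mean over the probe sets of a gene, and all probe sets. No named gene or list called outside its range changed sign under a scaling, and the log2 ratios of named genes moved by less than the spread of log2 ratios in 672 of 672 cases under each scaling. Median centring moved a ratio by at most 0.047, and the mean over probe sets could alter only 5 symbols, so these 2 are weak checks for single genes. List medians moved by more than their random spread in 17 of 102 cases under quantile normalization, 11 under lowess centring and 1 under median centring. Signs turned only for medians close to 0, such as costamere and oxidative phosphorylation genes in atria. The floor and the fold moved more, as they set how many genes can be counted, and the cause of the lower correlation without a floor was not tested. With no floor, 289 genes were higher in atria, 99 higher and 121 lower in ventricles, 7 went in opposite ways, and Pearson's correlation was 0.21. With the floor at the 75th percentile the counts were 35 higher and 80 lower in atria, 22 and 34 in ventricles, 253 higher in wild type atria, 9 the same way and 0 opposite. With the stricter fold they were 17 and 48 in atria, 14 and 22 in ventricles, 92 and 28 between wild type chambers, 11 the same way and 0 opposite, and the shares kept were 75% and 53.6%. Leaving out markers of other cell types and sex-linked genes left 1 gene with opposite directions. Genes near background are limited by signal, since RMA shrinks their ratios. No paired analysis was possible by replicate number because each group has 1 array, and leaving out replicates was not possible for the same reason. Pairing the arrays by chamber would leave 1 residual degree of freedom for genotype and was not run.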

Other observations

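The values in this part were chosen after the data were seen. Among circadian clock genes, Per2 was higher by 0.26 in atria and 0.38 in ventricles and Ciart by 0.52 and 0.62, while Npas2 (−0.32 and −0.26) and Arntl, which encodes BMAL1 (−0.14 and −0.22), were lower. Others differed less or not in the same way, with Nr1d1 at 0.01 in both chambers, Cry1 at 0.05 and −0.01, and Per3 at −0.11 in atria and 0.20 in ventricles, and of the list only Ciart in ventricles passed 1.5-fold. The platelet genes Ppbp, Pf4 and Gp9 were higher in wild type atria than in wild type ventricles by 2.52, 0.68 and 0.79. In knockout-labelled atria they were lower, at −2.12, −0.42 and −0.55, and stood at −0.04, −0.11 and −0.05 in ventricles, with only Ppbp past 1.5-fold. The platelet gene Itga2b was also higher in wild type atria, by 0.70, and stood at −0.23 in knockout-labelled atria and 0.23 in ventricles, while Gp1bb had 0.29, 0.22 and 0.11 in the same order.

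Partner genes did not always move together. Hadhb was at −1.74 in atria while Hadha, which encodes the other subunit of the same mitochondrial complex, was at −0.07. On the ventricular arrays Hadhb had the identical value of 9.08. In all, 124 probe sets had identical values on the 2 ventricular arrays and 65 on the 2 atrial arrays. The splicing factor gene Srsf3 (−1.44), Hmgb1 (−1.29) and the actin capping gene Capza1 (−1.28) were lower in knockout-labelled atria and stood at 0.19, 0.05 and 0.30 in ventricles. Of the tropomyosin genes, Tpm2 was higher by 1.47 in knockout-labelled ventricles, where Tpm1 was at −0.06. Tpm3 was higher by 0.92 in knockout-labelled atria, from 5.25, below the floor, to 6.16.

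Of the 222 genes at least 2-fold higher in wild type ventricles, 24 were at least 1.5-fold lower and 7 higher on the knockout-labelled ventricles array. Of the 288 chosen on the knockout-labelled pair instead, 9 were lower and 20 higher. Each choice shares an array with the comparison and pulls the counts its own way, so no direction is read from them.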
